A study of Mus musculus with 2 samples.

How the data were processed

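DNase-seq was done on heart tissue of mouse embryos (strain B6NCrl, embryonic day 10.5, pooled male and female). Per the labels there were 2 biological replicates from separate biosamples of 1 donor record, sequenced on a pair of Illumina instruments; both formed 1 group. The authors processed each library in a pair of rounds against build mm10. The aligner, the peak caller and the footprint caller are not given in the sources used here.

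From the later round, the deposited peak lists of variable width give a signal per peak. The signal is a whole multiple of a step of 0.00389619 in replicate 1 and 0.00357086 in replicate 2 (100% of values within 0.1 tag), so it was divided by the step to give tags per peak. If it were tags scaled to library depth, which no header states, the steps would imply 256.661 M and 280.045 M tags and 17.4 and 19.0 tags per median peak width at the genome average. The deposited description names no threshold for these lists. Set against the deposited track of FDR per base (a p-value type of unit, kept at 0.05 and lower), the highest best FDR of a peak was 0.0500 in the longer list of each library. In the shorter list all but 2 peaks of replicate 1 were at 0.001 or lower. The longer list was the main list and the shorter one the stricter alternative. From the earlier round, the deposited 150-bp peak lists give counts of tags, and the authors' hotspots (broad regions) give a −log10 FDR capped at 100 and a score 10 times as large. The deposited footprint lists hold the same p-value type of value, 0.01, throughout, taken as their FDR threshold. The FDR track of the earlier round was not used.

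Coordinates were set against the GRCm38 reference sequence and GENCODE M21 annotation, and all regions lay within the 21 chromosomes. Printed starts count from 1. Peak midpoints were used as positions. Peak values were divided by the median of their library's main list before libraries were compared. Peaks overlapping by at least 1 bp were called shared and merged with their partners into shared regions, placed by their own midpoint. Observed sharing was set against 100 placements of the other library's peaks shuffled over the same chromosomes. Shares carry 95% Wilson intervals, which cover counting error only. Tags per peak are given in the report and are not sequencing depth. Total reads per library were not used here.

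Midpoints were classed as promoter (within 1 kb of a TSS), UTR, coding exon, exon of a noncoding gene, intron or intergenic, and compared with the genome's bases. There were 19 lists with 288 marker genes, of which 287 were found in the annotation (not Ahsp). The share of each list with a promoter peak was compared with all other protein-coding genes by a two-sided Fisher's exact test. Distal peaks, over 1 kb from any TSS, were given to the nearest protein-coding TSS within 100 kb. The mean per gene was compared with 10000 random lists matched on decile of territory length (two-sided permutation test). Both families were adjusted by Benjamini-Hochberg over 57 tests. For 27 consensus motifs, 150-bp windows at distal midpoints were compared with windows 1000 bp upstream that overlap no peak, by an exact McNemar test, two-sided, adjusted over 54 tests. Footprints were set against 20 random placements in the same shared regions, and their motif matches against places of the same width in the same peaks. Genes and regions are not independent replicates, and with 2 libraries no difference between conditions was tested.

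The lists, motifs, tests, main alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names, from each heart or blood list, the 4 members with most shared distal regions, and from each other list 2; some of these genes were not used here. From all genes it names the 10 with most shared distal regions, those nearest the 5 strongest shared distal regions, and those nearest the 3 strongest peaks of each replicate without an overlapping peak in the other. Ties went to the higher promoter value. List members named as open or as exceptions, and the erythroid members with their ratios, were chosen after their values were seen.

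Alternatives were the stricter list, hotspots, 50% reciprocal overlap, equal numbers of strongest peaks, no scaling, a 2.5-kb promoter window, 50 kb for assignment, matching on list size only, 50-bp motif windows, dinucleotide-shuffled windows and each library alone. Leaving out 50-kb bins with at least 20 peaks in either library was added after the data were seen, as was the comparison of promoter ratios, in which random lists were matched on peak strength or on CpG content. The same ratio was taken at shared distal regions near list genes, less the median of distal regions of like strength and crowding, against random lists matched on the number of regions.

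The procedures were tested on simulated data with 200 lists of 20 genes. A list or motif was called there at an unadjusted p of 0.05 or lower. The rates given here therefore do not describe calls after adjustment. The distal test called 4% of lists with no change and 94.5% of lists with a 2-fold change when counts were even between genes, and 7.5% and 38.5% when they were uneven. The promoter test called 3.5% of lists planted at 65% open, 39% of lists planted at 85% and 95.5% of lists planted at 95%. The ratio test called 4.5% of unshifted lists of 13 genes and 65.5% of lists shifted by -0.5 on the log2 scale. With none planted, 2 of 27 motifs were called. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9 and bedtools 2.31.1.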

Results

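Open chromatin was mapped by DNase-seq in heart tissue of mouse embryos of strain B6NCrl at embryonic day 10.5, pooled from males and females. The enzyme DNase I cuts DNA that is free of nucleosomes, so clusters of cuts (peaks) mark promoters, enhancers and insulators that are accessible in the tissue. There was 1 group with 2 libraries, biological replicates 1 and 2, and no treatment or second tissue. The comparisons made were therefore replicate against replicate, marker genes of the heart against all other genes, and peak sequence against neighbouring sequence. Replicate 1 held 386169 peaks covering 70.9 Mb, and replicate 2 held 253685 peaks covering 47.9 Mb. The median peak was 180 bp wide in both libraries and held 54 tags in replicate 1 and 58 in replicate 2. Under the authors' earlier processing, peaks of fixed width held 44.9 M tags in replicate 1 and 28.8 M in replicate 2. If the peak signal were tags scaled to library depth, which no header states, these would be 17.5% and 10.3% of all tags. The implied totals would be 256.661 M in replicate 1 and 280.045 M in replicate 2, so more tags in peaks do not make replicate 1 the deeper library. Every peak value is 1 measurement per library, and intervals on shares are 95% Wilson intervals that cover counting error only.

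Strong peaks were mostly found in both libraries, and weak peaks mostly in 1 library only. Of the peaks of replicate 1, 24.8% (95% interval 24.7 to 25) overlapped a peak of replicate 2, and 37.8% (37.6 to 38.0) of those of replicate 2 overlapped a peak of replicate 1. Random placement of the other library's peaks gave 3.85% and 5.79%, so the observed shares were 6.45 and 6.53 times the random ones. Peaks found in both held a median of 164 tags in replicate 1 and 138 in replicate 2, against 46 and 44 for those found in 1 library. In the decile with the fewest tags, 7.11% of replicate 1 peaks and 7.5% of replicate 2 peaks were shared, and in the decile with the most tags 92.4% and 97.9% were. Merging overlapping peaks of both libraries gave 89209 shared regions, 60208 of them distal (over 1 kb from any annotated transcription start site, TSS) and 29001 at promoters.

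**Figure D1:**
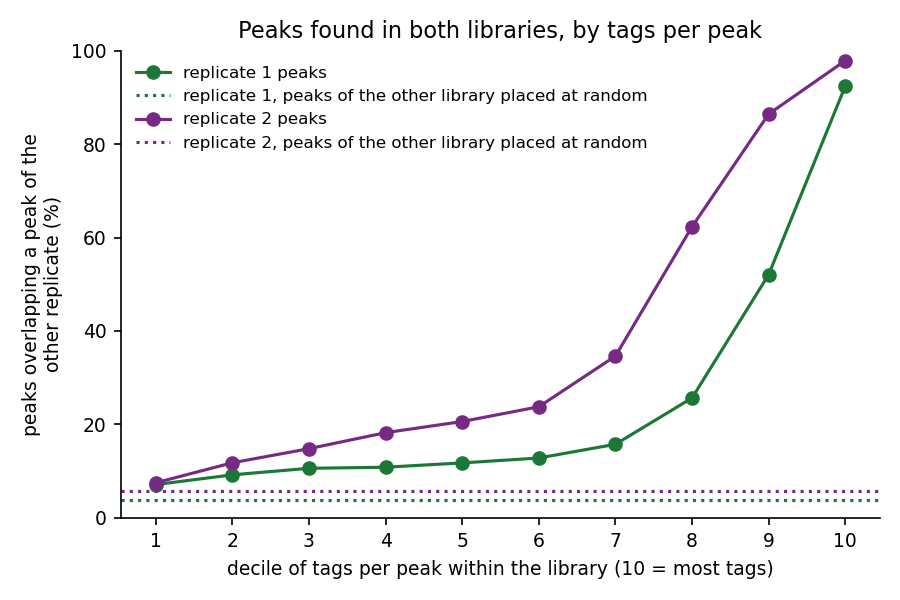
Share of peaks (%) that overlap a peak of the other replicate, by decile of tags per peak within each library; dotted lines give the mean share when the other library's peaks were placed at random. Sharing rises from 7.11% and 7.5% in the first decile to 92.4% and 97.9% in the last.

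The strongest peaks without an overlapping partner lay at promoters with a partner next to them. In replicate 1 these were at Nectin2 (chromosome 7, 19749601 to 19749680, 2054 tags), at C2cd3 (chromosome 7, 100371861 to 100372100, 1964 tags) and at Cactin (chromosome 10, 81320321 to 81320560, 1505 tags). In replicate 2 they were at C2cd3 (chromosome 7, 100372101 to 100372180, 1592 tags), at Atf5 (chromosome 7, 44815721 to 44816020, 1562 tags) and at Nectin2 (chromosome 7, 19749701 to 19749780, 1501 tags). The gap to the nearest peak of the other library was 20 bp at Nectin2 and 0 bp at the others, so peaks of both libraries lay side by side at these promoters. Over all peaks, allowing a gap of 150 bp raised the shared percentage only to 28.4% in replicate 1 and 42.5% in replicate 2. Requiring a reciprocal overlap of 50% lowered it to 15.9% and 24.3%.

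Shared regions that were strong in replicate 1 were strong in replicate 2. Across the 89209 regions the log2 peak values correlated with Pearson r = 0.92 and Spearman rho = 0.92; regions are not independent replicates, and no p-value was computed. Values scaled to the median peak of each library differed by less than 2-fold at 80.2% of regions. They were over 2-fold higher in replicate 1 at 15005 regions (16.8%) and in replicate 2 at 2661 (2.98%). The median log2 ratio of replicate 1 over replicate 2 was 0.38 (SD 0.68 over regions). It was 0.65 at promoter regions and 0.22 at distal regions, 0.38 on the X chromosome (1933 regions) and 0.18 on the Y chromosome (40 regions). With 1 library on each side these ratios describe the libraries and test no condition.

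The promoters of erythroid genes, which serve the primitive red blood cells that circulate through the heart tube at this age, were relatively stronger in replicate 2. Their median log2 ratio was -0.23 (13 genes), against 0.78 for random promoter lists of the same size and peak strength (central 95% of lists 0.47 to 1.08). The adjusted p was 0.0032 over 16 lists (permutation of 10000 random lists; the raw p of 0.0002 is the smallest possible), and 11 of 13 genes lay below the random median. The embryonic globin gene Hbb-y had a ratio of -0.74 and the embryonic globin gene Hba-x one of -0.63. Klf1, a regulator of globin genes, was at -0.40, the anion exchanger gene Slc4a1 at -0.33, Hbb-bh1 at -0.30, the haem synthesis gene Alas2 at -0.28 and Gata1 at -0.23. Tfrc (0.73), Gfi1b (0.98) and Tal1 (1.21) lay among promoters in general, whose median was 0.73 (14285 genes). The cardiac transcription factor list (0.45) and the sarcomere list (0.42) also lay below random lists matched on peak strength, with differences of -0.39 and -0.38 (adjusted p 0.0203 for both). Against random lists matched on CpG content the differences were -0.25 (13 of 19 genes below) and -0.19 (18 of 24), and neither passed (adjusted p 0.542 for both). For members outside 50-kb bins with at least 20 peaks in either library, matched on peak strength, they were -0.078 (5 of 9) and -0.23 (10 of 12). Neither passed there (adjusted permutation p 0.670 and 0.546). These list comparisons were chosen after the ratios had been seen.

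**Figure D2:**
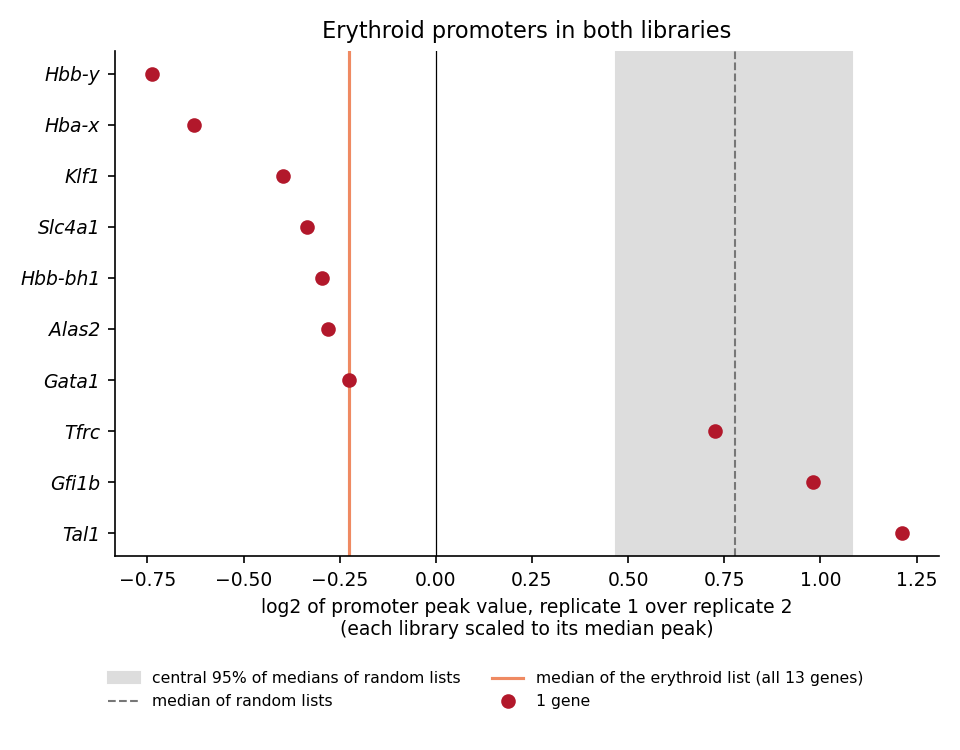
Log2 ratio of the promoter peak value in replicate 1 over replicate 2, each scaled to its library's median peak, for the 10 erythroid genes named in the text (points). The grey band is the central 95% of the medians of random lists matched on peak strength (0.47 to 1.08), and the median of all 13 genes of the list is -0.23.

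Shared open regions were concentrated at promoters. Of the 89209 shared regions, 32.5% (32.2 to 32.8) had their midpoint within 1 kb of a TSS, which makes up 6.05% of the genome, a 5.37-fold excess. Another 31.4% lay in introns, 31% between genes, 2.18% in coding exons (2.32 times the genome's share), 1.47% in 3′ UTRs, 1.35% in exons of noncoding genes and 0.0796% in 5′ UTRs outside the promoter window. Among the strongest 10% of shared regions 89.7% (89.1 to 90.4) were promoters, a 14.8-fold excess. Peaks found in replicate 1 alone were at promoters in 11.1% of cases and those found in replicate 2 alone in 9.29%. Promoters made up a smaller share of each library on its own, 16.6% in replicate 1 and 18.5% in replicate 2. Of 21853 protein-coding genes, 14301 (65.4%) had a shared region at a promoter, 73.6% had a peak there in replicate 1 and 68.5% in replicate 2.

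Promoters of the contractile apparatus and of the cardiac regulators were open in nearly every case, where open means that a region shared by both libraries lay within 1 kb of a TSS. All 24 sarcomere and cardiomyocyte genes were open (100% against 65.4% of other genes; Fisher's exact test, two-sided, adjusted p = 0.000673). Among them were Tpm1 (tropomyosin), with peaks 31.7 and 17.9 times the median peak of replicates 1 and 2, Myl4 (atrial light chain), at 30.6 and 26.1 times, and Ttn (titin), at 9.94 and 9.48 times. Of the 20 cardiac transcription factors 19 were open (95%, adjusted exact p = 0.0152): Gata6 reached 14.0 and 11.5 times the median, Hand2 13 and 9.62, Nkx2-5 8.70 and 6.38, and the exception was Irx4, with a promoter peak in replicate 1 only (4.26 times). The cushion and neural crest mesenchyme list, cells that build valves and outflow septum, was open at 15 of 16 genes (adjusted exact p = 0.0366); Pdgfra was at 15.8 and 6.48 and Sox10, a neural crest and glial regulator, was the exception, with a peak in replicate 1 only (3.20 times).

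The erythroid list was open at 13 of 13 genes (adjusted exact p = 0.0199) and the housekeeping list at 16 of 16 (adjusted p = 0.0117), with Eef1a1 at 32 and 23.9 times the median and Ywhaz at 27.6 and 20.8. The other heart lists lay above other genes in the main peak lists without passing the test. They were cardiac ion handling (14 of 16, adjusted exact p = 0.120; not Kcnq1 or Casq2), epicardium (10 of 11, 0.176; not Msln), second heart field (9 of 10, 0.263; not Bmp4, whose peaks in the 2 libraries did not overlap) and endothelium and endocardium (14 of 18, 0.417; not Emcn, Eng, Sox18 or Nos3). In replicate 1 alone, the library with more peaks, endothelium (18 of 18, adjusted exact p = 0.0199) and ion handling (16 of 16, adjusted p = 0.0246) did pass. Over all heart lists 105 of 115 promoters were open.

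Most promoters of macrophage, liver, gut, pancreas and T cell genes lacked a shared region. Of 12 macrophage genes 0 were open (adjusted exact p = 7.59e-05), although Spi1, a myeloid regulator, had a promoter peak in replicate 2 (2.67 times the median), as had Adgre1 (0.621), and Cd68 had one in replicate 1 (2.94). Of 16 hepatocyte genes only Trf, which encodes transferrin, was open (adjusted exact p = 7.32e-05). The intestine list was open at 2 of 12 genes (Lgr5 and Krt20; adjusted exact p = 0.00477), the pancreas list at 3 of 12 (Ptf1a, Nkx6-1 and Mafa; adjusted p = 0.0181) and the T cell list at 4 of 14 (Cd3d, Tcf7, Bcl11b and Gata3; adjusted p = 0.0230). In replicate 1 alone pancreas (8 of 12, adjusted exact p = 0.576), intestine (6 of 12, 0.154) and T cell (8 of 14, 0.307) did not pass, and in replicate 2 alone pancreas (7 of 12, 0.576) did not. The remaining lists did not pass the test: neuron (14 of 18, adjusted exact p = 0.417), posterior Hox (9 of 16, 0.534), skeletal muscle (10 of 19, 0.323), pluripotency (6 of 12, 0.448) and keratinocyte (4 of 12, 0.0590). Of these, neuron lay as far above other genes as endothelium did (77.8% against 65.4%). In replicate 1 alone it reached 17 of 18 (adjusted exact p = 0.105).

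The sarcomere, macrophage and hepatocyte calls held under every alternative run, and the others did not. Crowded bins, 50-kb bins with at least 20 peaks in either library, held many of the genes concerned. Without them, of the 5 lists above other genes only sarcomere passed (12 of 12, adjusted exact p = 0.0264), and of the 5 below only macrophage and hepatocyte (0 of 11 each, adjusted p = 0.00114). The other calls ended with fewer genes at differences from other genes of like size: cardiac transcription factors were open at 9 of 9, housekeeping at 9 of 9, erythroid at 7 of 7, cushion mesenchyme at 9 of 10, T cell at 2 of 10, intestine at 2 of 9 and pancreas at 1 of 7, against 60.1 to 60.2% of other genes. With the authors' stricter peak list the lists above were sarcomere (22 of 24, adjusted exact p = 0.00338) and housekeeping (16 of 16, 0.00297), and pancreas was no longer below. That list also turned endothelium (7 of 18, 38.9% against 58.5% of other genes) and epicardium (6 of 11, 54.5% against 58.5%) below other genes, without passing the test. With a promoter window of 2.5 kb cushion mesenchyme, pancreas and T cell did not pass, and with hotspots pancreas did not. Hotspots added ion handling (15 of 16, adjusted exact p = 0.0383) and second heart field (10 of 10, 0.0419). In replicate 1 alone erythroid (13 of 13, adjusted exact p = 0.0561) and in replicate 2 alone cushion mesenchyme (15 of 16, 0.0590) fell short.

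**Figure D3:**
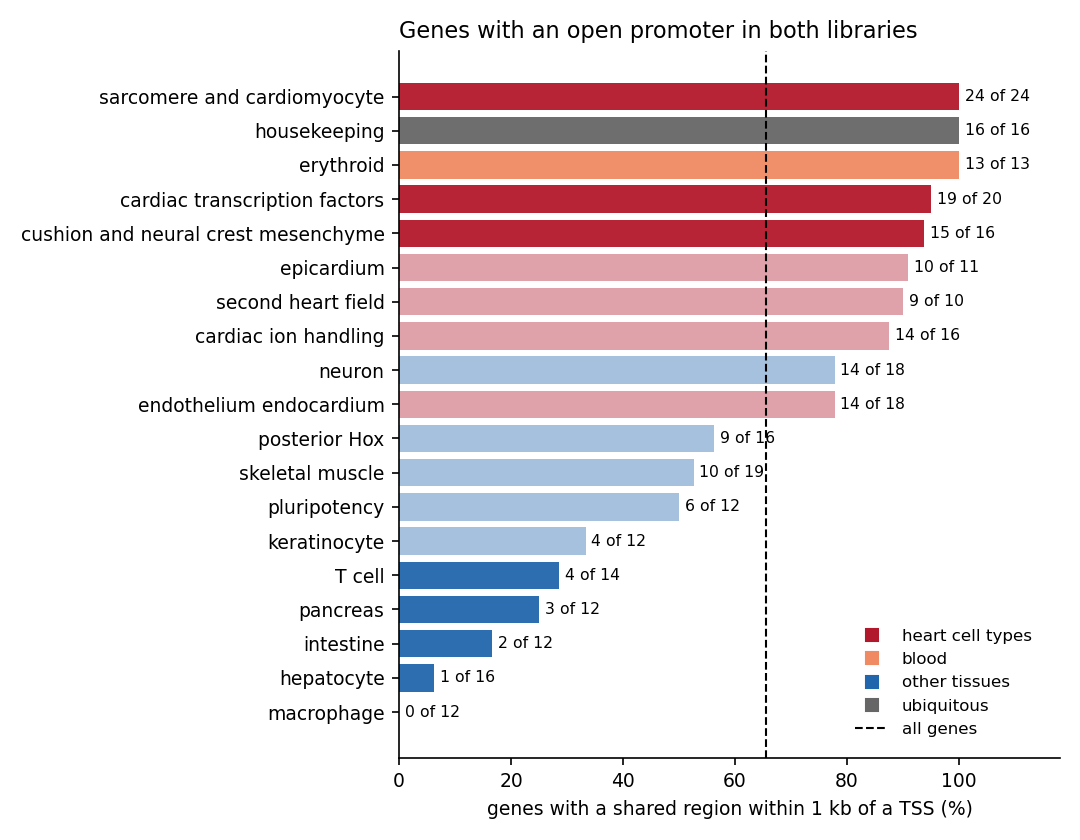
Percentage of the genes of each list with a region shared by both libraries within 1 kb of a TSS, with counts beside the bars; solid bars passed Fisher's exact test at adjusted p under 0.05, pale bars did not, and the dashed line marks all protein-coding genes (65.4%). The sarcomere, housekeeping and erythroid lists reach 100%, and macrophage lies at 0 of 12.

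Genes of cardiac transcription factors had the highest mean number of shared distal regions among the lists, although the list did not pass adjustment. Each shared distal region was given to the nearest protein-coding TSS within 100 kb, which left a mean of 2.23 and a median of 1 region per gene, and none at 45.2% of genes. The 20 cardiac transcription factors had 9.15 ± 6.75 (SD over genes) shared distal regions each, 2.23 times the 4.10 of random lists matched on territory length. The 24 sarcomere genes had 4.71 ± 5.91, 2.40 times the 1.96 of random lists. In replicate 1 cardiac ion handling had a higher mean (48.7) than the cardiac transcription factors (44.4), and no test compared lists with each other. In the shared regions the cardiac transcription factors and the sarcomere genes had raw permutation p-values of 0.0034 and 0.0082. Neither of these 2 lists passed adjustment over the 57 tests (adjusted p 0.108 and 0.117). No list passed in any of the 3 peak sets by this test, and 5 of the 57 tests had an unadjusted p under 0.05, 2 of them in the shared regions. The others were cardiac transcription factors (2.00-fold, permutation p = 0.0066), sarcomere (2.09-fold, p = 0.0120) and ion handling (2.22-fold, p = 0.0038) in replicate 1; none was in replicate 2. In replicate 2 alone the ratios were 1.51 for cardiac transcription factors (permutation p = 0.133), 1.29 for sarcomere (0.425) and 1.22 for ion handling (0.5).

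The cardiac transcription factor list did pass under 3 alternatives: random lists matched on size only (4.11-fold, adjusted permutation p = 0.0038), hotspots in place of peaks (2.35-fold, 0.0228) and leaving out the crowded bins (2.37-fold, 0.0076). Matching on size only does not control territory length, so that pass cannot separate the list from genes with long territories. The mean of random lists was 2.23 there, against 4.10 with matching on territory length. The list did not pass with assignment within 50 kb (2.47-fold, adjusted permutation p = 0.0912) or with the stricter list (2.38-fold, 0.45). Leaving out the crowded bins also brought the sarcomere list past the threshold (2.72-fold, adjusted permutation p = 0.0171).

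Nkx2-5, the homeobox regulator of early heart cells (chromosome 17, 26838664 to 26845009, ENSMUSG00000015579.5), had 25 shared distal regions, more than any other heart list member, and all of them lay in crowded bins. Gata6 (chromosome 18, 11052064 to 11085635) had 20, with 5 outside crowded bins, Hand2 (chromosome 8, 57320983 to 57324633) had 20, with 3 outside, and Smyd1, a muscle methyltransferase gene, had 16, with 2 outside. Among sarcomere genes the counts were 23 at Ttn (chromosome 2, 76703980 to 76982547; 5 outside), 17 at Myl4 (chromosome 11, 104550663 to 104595753; 0 outside), 13 at Myl2, the ventricular light chain gene (6 outside), and 10 at Tpm1 (6 outside). A bin crowded in both libraries held the start of 13.9% of heart list genes, 18.8% of housekeeping genes, 10.7% of genes of the other tissue lists and 4.97% of all protein-coding genes.

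The other heart lists had 1.17 to 1.67 times the regions of random lists. Cardiac ion handling stood at 6.81 per gene (1.67-fold, permutation p = 0.106), led by the calcium channel gene Cacna1c with 22 (0 outside crowded bins; 271 distal peaks in replicate 1 and 37 in replicate 2), the pacemaker channel gene Hcn4 with 13 (4 outside), Kcnh2 with 12 (6) and the calcium pump gene Atp2a2 with 7 (0). Endothelium and endocardium had 3.89 (1.17-fold), with 12 at Flt1 (3 outside) and 12 at Cdh5 (3), 9 at the endocardial regulator Nfatc1 (4) and 7 at Fli1 (4). Cushion and neural crest mesenchyme had 5.12 (1.23-fold), with 15 at Msx2 (1 outside), 13 at Tfap2a (1), 10 at Pdgfra (4) and 9 at Foxc1 (3). Epicardium had 4.36 (1.49-fold), with 11 at Wt1 (0 outside), 9 at Tcf21 (4), 6 at Tbx18 (1) and 6 at Lrrn4 (1). The second heart field list, progenitors added at the poles of the heart tube, had 4.10 (1.21-fold), with 11 at Wnt11 (11 outside), 7 at Mab21l2 (7) and 6 at Hoxb1 (3). With the stricter list cushion mesenchyme (0.967) and second heart field (0.852) fell under random lists, and in replicate 2 alone second heart field (0.569) and endothelium (0.940) did.

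The erythroid list had 3.15 regions per gene (2.26-fold, against 1.47 and 1.25 in replicates 1 and 2 alone, permutation p = 0.0884), with 12 at Tal1 (0 outside crowded bins), 8 at Slc4a1 (0) and 4 at Hbb-y (4). Macrophage genes had 1.42 (0.771-fold), with 3 at C1qa, 3 at Ptprc, 2 at Adgre1 and 2 at Cx3cr1. Housekeeping genes (2.94, 2.10-fold, permutation p = 0.0948), with 11 at Ywhaz and 9 at Eef1a1, and posterior Hox genes (1.62, 2.08-fold, permutation p = 0.143), with 7 at Hoxa13 and 4 at Hoxd12, also lay above random lists without passing. Posterior Hox fell to 0.726 with matching on size only and to 0.742 without crowded bins. Skeletal muscle stood at 2.89 (1.39-fold), with 17 at Pax3 (2 outside) and 8 at Myh3.

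The other 7 lists, of other organs, were under random lists in the shared regions, and each of these turned above 1 under at least 1 alternative. Neuron had 2.39 regions per gene (0.660-fold, permutation p = 0.346), with 6 at Neurog2 and 5 at Gad1, and hepatocyte 1.5 (0.948-fold), with 11 at Ttr (0 outside crowded bins) and 5 at Trf (0). T cell stood at 2.00 (0.958-fold), with 9 at Cd2 and 8 at Bcl11b, and pluripotency at 2.17 (0.758-fold), with 7 at Nanog and 6 at Sox2. Keratinocyte stood at 1.58 (0.902-fold), with 5 at Cdh3 and 4 at Krt14, pancreas at 2.08 (0.697-fold), with 6 at Ins2 and 6 at Nkx2-2, and intestine at 1.75 (0.765-fold), with 5 at Fabp1 and 4 at Cdx2. A region near Cd2 or Fabp1 belongs to the nearest start site by distance alone, and the gene it acts on was not measured.

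**Figure D4:**
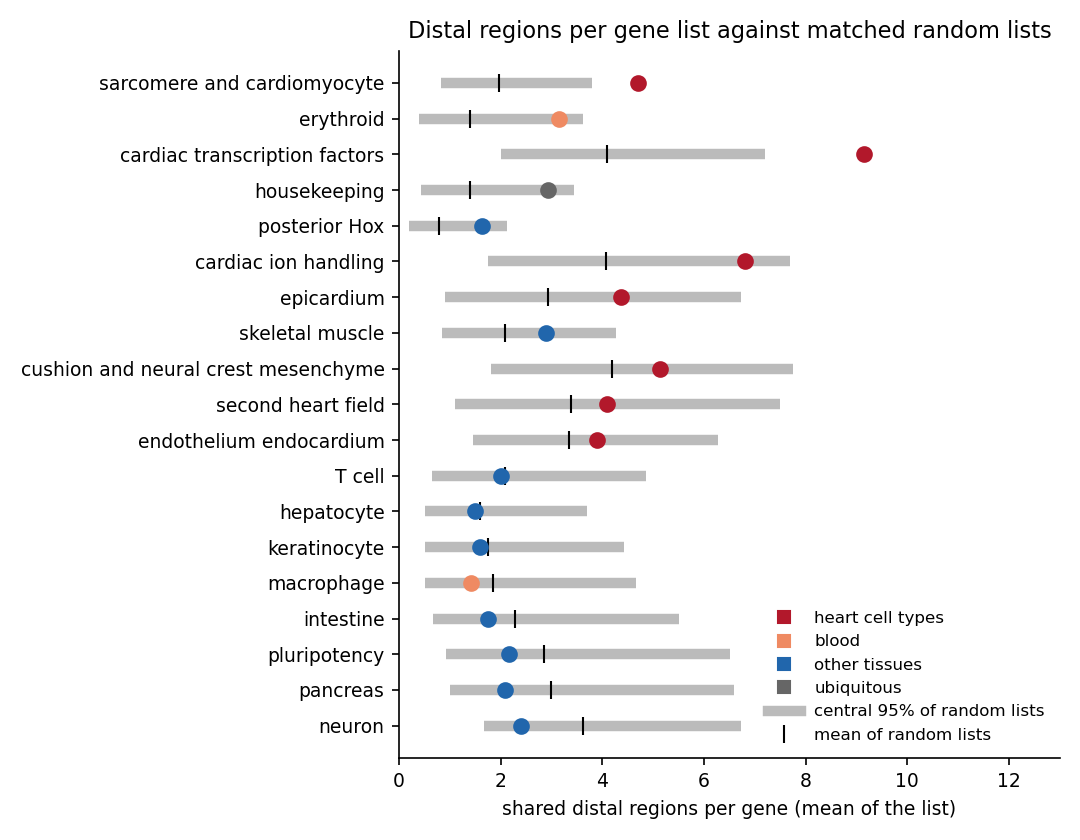
Mean number of shared distal regions per gene of each list (points), with the mean (tick) and the central 95% (grey bar) of 10000 random lists matched on territory length. Only the cardiac transcription factor list (9.15) and the sarcomere list (4.71) lie to the right of their bars, and neither passed adjustment.

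The genes with most shared distal regions of all were not heart markers. They were Zfp618 (62), Sgms1 (58), Svil (58), Cacna1b (57), Gm10320 (57), Abcc1 (56), Tmem241 (54), Cnih3 (54), Abat (53) and Agpat4 (53), and between 0 and 6 regions of each lay outside crowded bins. The 5 strongest shared distal regions were a site in the 3′ UTR of Limd1 (chromosome 9, 123461981 to 123462060; 10465 and 6748 tags in replicates 1 and 2), an intergenic site 5.49 kb from the start of Cd209a (chromosome 8, 3754381 to 3754560; 6857 and 3700 tags), an intronic site 28.9 kb from the start of Jarid2 (chromosome 13, 44869561 to 44869700; 6070 and 3120 tags), an intergenic site 35.5 kb from Pak3 (chromosome X, 143482981 to 143483140; 3922 and 4691 tags) and an intronic site 652 kb from the start of Il1rapl1 (chromosome X, 87238321 to 87238460; 5337 and 1650 tags). Of the 24-base words in these 5 sites a median of 42.3% also occurred elsewhere in the genome (6.37 to 87.7%).

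Sites of the insulator protein CTCF were the motif most concentrated at distal peaks. A match stood in 2.10% of the 211101 windows of replicate 1 against 0.0388% of flanking windows 1 kb away (54.0-fold), and in 2.29% of the 139334 windows of replicate 2 against 0.0610% (37.5-fold). The GC-rich motif of the SP and KLF factors was 3.29 and 2.82 times as frequent as in the flanks, the REST half-site 2.69 and 2.76 times, the RFX motif 2.67 and 2.92 times, and the NRF1 motif 2.00 and 5.50 times. The E-box of the MYOD class was 2.01 and 2.05 times as frequent and the PU.1 motif 1.84 and 1.86 times. Among motifs of heart regulators, TEAD sites were in 4.98% of replicate 1 windows (1.45-fold, adjusted p = 2.25e-139, exact McNemar test) and 5.39% of replicate 2 windows (1.56-fold, adjusted p = 6.69e-138). MEIS sites (1.39 and 1.45-fold), ETS sites (1.37 and 1.39), the HAND class E-box (1.24 and 1.28) and T-box sites (1.20 and 1.31) were also above the flanks. AP-1 (1.37 and 1.55), p53 half-sites (1.13 and 1.11) and NF-Y (1.08 and 1.11) were above as well. The HAND and NEUROD E-boxes are reverse complements of each other and count the same sites.

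Sites of GATA, forkhead and octamer factors were less frequent at peaks than in the flanks. GATA sites stood at 0.760 and 0.788 of the flank share, forkhead sites at 0.769 and 0.732, octamers at 0.579 and 0.536, RUNX at 0.862 and 0.870, the SRF motif at 0.842 and 0.850, NKX2 sites at 0.919 and 0.891 and HNF1 sites at 0.25 and 0.312. MEF2 sites were at 0.890 in replicate 1 (adjusted exact p = 0.0484) and 1.00 in replicate 2, and SOX sites at 0.984 and 0.946, past the threshold in replicate 2 only (adjusted p 0.244 and 0.000642). HNF4 sites and the OCT4-SOX2 composite did not pass in either library. The stricter peak list ended the calls for MEF2 in replicate 1, NF-Y in replicate 1 and SOX in replicate 2, and windows of 50 bp those for p53 and HNF1 in both. Peak windows held 50.9% GC in replicate 1 and 51.0% in replicate 2, and their flanks 43.1% and 42.7%.

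Against windows shuffled to keep each window's own dinucleotides, several of these directions turned, not all of them past the threshold. MEF2 sites were then 2.75 and 3.17 times as frequent in peaks, forkhead sites 1.40 and 1.37, octamers 1.32 and 1.30, RUNX 1.26 and 1.29, HNF1 2.17 and 1.20, and GATA 1.01 and 1.06. T-box sites fell to 0.836 and 0.838, NF-Y to 0.703 and 0.728, MEIS to 0.987 and 0.975, AP-1 to 0.964 and 0.997 and p53 half-sites to 0.978 and 0.958. SOX sites turned in both (1.01 and 1.06). Of the turned ratios, those of HNF1 (adjusted exact p 0.196 and 1) and p53 (0.323 and 0.122) in both libraries, of MEIS in replicate 1 (0.0512), of SOX in replicate 1 (0.277) and of AP-1 in replicate 2 (0.887) did not differ from 1 by the exact McNemar test. TEAD (1.32 and 1.42), ETS (1.54 and 1.62), the HAND class E-box (1.17 and 1.17) and RFX (3.47 and 3.20) stayed above 1, as did CTCF (15.9 and 20.5), SP and KLF (7.14 and 6.58), NRF1 (8.30 and 18.0), REST (1.33 and 1.34) and the MYOD class E-box (1.10 and 1.08).

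**Figure D5:**
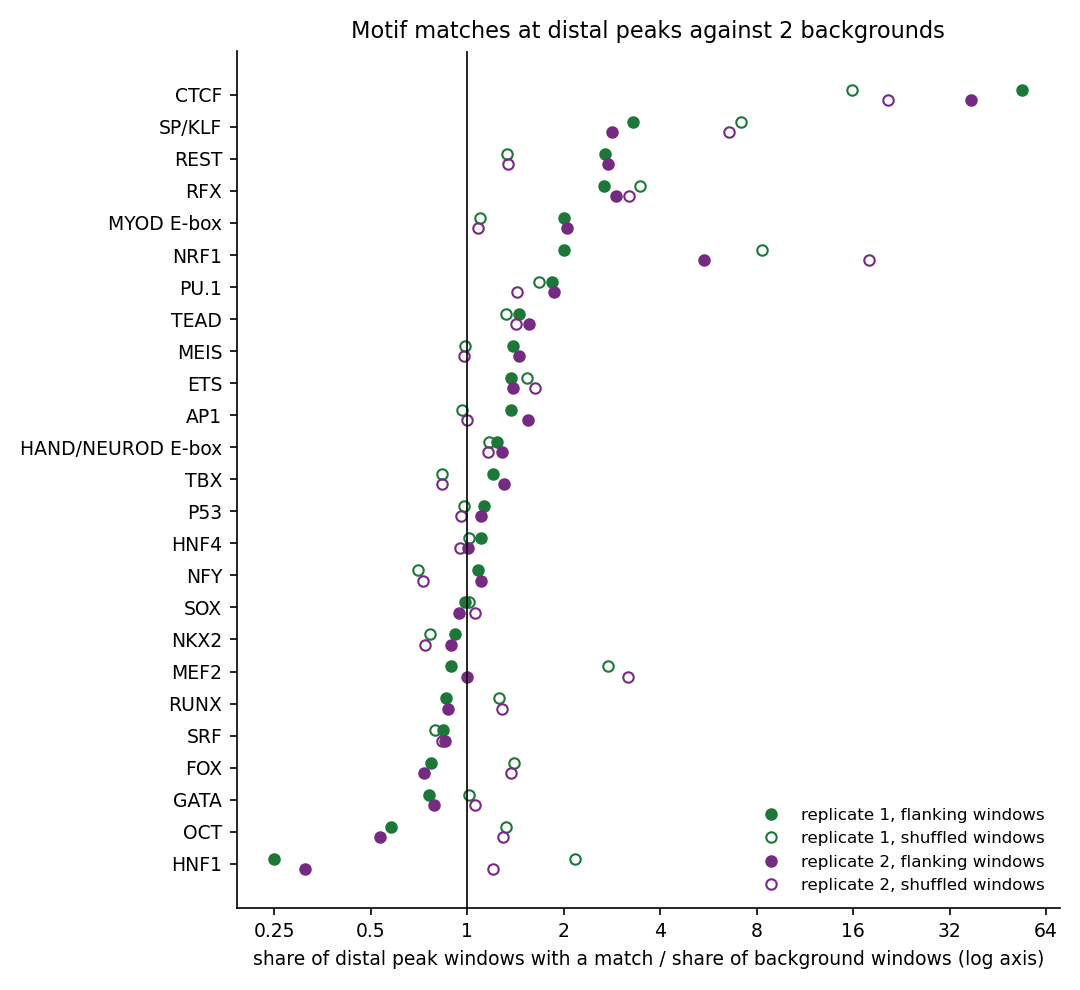
Share of 150-bp windows at distal peaks with a motif match divided by the share in background windows, on a log axis, for each library against flanking windows (filled) and dinucleotide-shuffled windows (open). CTCF lies far to the right under both backgrounds, while MEF2, forkhead, octamer, T-box and NF-Y change sides.

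Footprints, short stretches inside peaks protected from DNase I, held CTCF sites and sites of GC-rich motifs more often than 1 random placement in the same peaks did. The authors' lists held 623466 footprints in replicate 1 (median width 9 bp) and 304522 in replicate 2 (8 bp), and 86.3% and 89.7% of them lay in peaks. Footprints in peaks held the midpoint of a CTCF match 3.30 times as often in replicate 1 and 5.02 times in replicate 2 as windows of the same width placed at random in the same peaks. The ratios were 2.54 and 3.32 for REST, 2.34 and 2.82 for SP and KLF, 2.14 and 3.47 for RFX, 2.13 and 3.50 for NRF1, 1.35 and 1.64 for the MYOD class E-box, and 1.25 and 1.43 for ETS. GATA (0.748 and 0.731), forkhead (0.461 and 0.45), MEF2 (0.495 and 0.613), TEAD (0.880 and 0.768) and MEIS (0.816 and 0.711) were under 1. So were motifs outside the heart class, such as octamers (0.630 and 0.533), RUNX (0.752 and 0.583) and NF-Y (0.814 and 0.763). The random windows were not matched on GC, so these low ratios do not show that the factors leave no footprints. In shared regions 33.2% (33.1 to 33.4) of replicate 1 footprints overlapped one of replicate 2, and 47.6% (47.3 to 47.8) of those of replicate 2 overlapped one of replicate 1. Random placement in the same regions gave 18.5% and 25.6%, so the shares were 1.80 and 1.85 times random. Reciprocal overlap of 50% lowered the shares to 22.1% and 31.9%. The footprint motif ratios carry no test.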

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

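The alternative without crowded bins (50-kb bins with at least 20 peaks in either library) was chosen only after the data were seen; the other alternatives given here were planned. No paired analysis was possible because there is 1 group with 2 libraries. For each alternative that moved a result the cause was not tested, except where fewer peaks or genes entered by construction.

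The stricter list held 256250 peaks in replicate 1 and 165603 in replicate 2, and 156390 and 112276 peaks of the main lists lay outside crowded bins. The share of replicate 1 peaks overlapping replicate 2 was 15.9% with reciprocal overlap, 21.5% with the stricter list, 33% with equal numbers of strongest peaks, 26.0% with hotspots and 31% without crowded bins. For replicate 2 these were 24.3%, 33.3%, 33.3%, 41.0% and 43.3%. The share of footprints shared fell with reciprocal overlap to 22.1% and 31.9%. The median log2 ratio, 0.38, was 0.40 to 0.46 under its alternatives.

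The promoter share of shared regions was 42.3% with a 2.5-kb window, 41.0% with the stricter list, 36.0% with equal numbers, 38.6% without crowded bins, and 16.6 to 18.5% in single libraries. Introns and intergenic sequence held 54.3%, 54.2%, 58.9%, 57.3% and 76.3 to 77.7% in the same order.

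Of promoter list results 82 kept direction and side of the threshold, 21 became weaker, 4 stronger and 7 reversed, none of the reversed past the threshold. With the stricter list endothelium (38.9%), epicardium (54.5%) and neuron (55.6%) fell under other genes. In single libraries posterior Hox (75 to 81.2%) rose above them in both, and skeletal muscle (52.6 to 73.7%) and pluripotency (58.3 to 75%) in replicate 1. The number of lists above other genes, 5, was 2 with the stricter list and 1 without crowded bins, where fewer genes were left at differences of like size. The number below, 5, was 3 with the 2.5-kb window, 2 without crowded bins and 2 to 4 in single libraries, with 2 without replicate 2. Of distal list results 102 kept direction and side, 4 became stronger and 27 reversed without passing. The stricter list gave 0.967 for cushion mesenchyme, 0.852 for second heart field and 1.27 for hepatocyte. Assignment within 50 kb gave 1.02 for hepatocyte, 1.05 for T cell and 1.02 for intestine; matching on size only gave 1.07 for neuron and 0.726 for posterior Hox; hotspots gave 1.02 for T cell, 1.01 for keratinocyte and 1.14 for intestine. Without crowded bins the ratios were 1.32 for macrophage, 1.58 for T cell, 1.20 for pluripotency, 1.25 for keratinocyte, 1.20 for intestine and 0.742 for posterior Hox. In single libraries they were 0.940 to 1.24 for endothelium, 0.569 to 1.31 for second heart field, 0.901 to 1.57 for hepatocyte, 0.946 to 0.957 for skeletal muscle, 0.746 to 1.40 for T cell, 0.447 to 1.81 for pluripotency, 0.760 to 1.15 for keratinocyte and 1.07 to 1.14 for pancreas. The number of lists above random, 0 by the permutation test (2 at an unadjusted p under 0.05), was 1 with matching on size only, 1 with hotspots and 2 without crowded bins.

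Motif results depended on the background. Of the ratios 177 kept direction and side, 27 reversed, 8 became weaker and 2 stronger. The number of depleted motifs, 8 in each library, was 5 and 5 against shuffled windows, and 25 of the reversals arose there. In replicates 1 and 2 the reversed ratios were 1.01 and 1.06 for GATA, 0.836 and 0.838 for T-box, 0.987 and 0.975 for MEIS, 1.40 and 1.37 for forkhead, 0.703 and 0.728 for NF-Y, 0.964 and 0.997 for AP-1, 2.17 and 1.20 for HNF1, 1.32 and 1.30 for octamers, 1.26 and 1.29 for RUNX, and 0.978 and 0.958 for p53. MEF2 reversed in replicate 1 (2.75) and SOX in both (1.01 and 1.06). OCT4-SOX2 in replicate 1 (3) and HNF4 in replicate 2 (0.948) reversed from ratios that had not passed, as did SOX in replicate 1 with the stricter list (1.02) and HNF4 in replicate 2 without crowded bins (0.941).

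Selecting the stricter 50% of footprints, or equal numbers of the strongest, was not run because every footprint has the same value. What depth limits was not tested; sharing was lowest among peaks with few tags.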

Other observations

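The tests of motifs at shared distal regions were chosen only after the result was seen, as were those of copy number, of the caller's threshold, of repeats in the 5 strongest regions and of CpG content; the others were set before their own values were seen.

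At distal regions open in both libraries, sites of MEF2, a regulator of muscle genes, were more frequent than in both backgrounds. MEF2 sites were in 0.620% of 38570 windows, 1.78 times their share in the flanks (adjusted exact p = 9.42e-08), and 8.08 times that in 60207 shuffled windows. TEAD sites were 1.89 and 1.71 times as frequent as in these backgrounds, MEIS sites 1.71 and 1.16, AP-1 sites 1.91 and 1.23, REST sites 4.92 and 2.12, RFX sites 6.26 and 7.5, SP and KLF sites 4.65 and 7.5, and CTCF sites 133 and 43.8. The MYOD class E-box (2.54 and 1.18), PU.1 (2.14 and 1.86), NRF1 (11 and 10.5), ETS (1.46 and 1.72) and the HAND class E-box (1.27 and 1.23) were also above both. Lying above both backgrounds was therefore not particular to motifs of heart regulators. Shared regions were not tested against the peaks of 1 library. GATA sites stayed under the flanks (0.890) and above shuffles (1.35), as did forkhead sites (0.714 and 1.69), and T-box sites were above the flanks (1.29) but not above shuffles (1.01, adjusted exact p = 0.838). NKX2 sites did not pass the test against the flanks (0.945, adjusted exact p = 0.143) and were less frequent than in shuffles (0.834, adjusted exact p = 1.49e-10). Outside crowded bins the ratios for MEF2 were 1.74 and 12.1 and for TEAD 1.96 and 2.05.

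Erythroid promoters leaned to replicate 2, with a median log2 ratio of -0.23 against 0.78 for random lists matched on peak strength. Crowded bins were argued against, since the 7 members outside them also had a median of -0.23, beyond the central 95% of random lists (0.27 to 1.09). Low CpG content was argued against as the whole cause, since the list lay at -0.84 from random lists matched on it. More blood cells in replicate 2 stay open: at 41 distal regions near the 13 genes the ratio lay at -0.18 relative to distal regions of like strength and crowding (9 of 13 genes below), inside the central 95% of random lists (-0.23 to 0.27; permutation p = 0.114, two-sided; adjusted p = 0.330 over 19 lists), and the endothelium (-0.25, p = 0.0108) and ion handling (-0.20, p = 0.0264; adjusted p 0.125 and 0.129) lists leaned further, so this does not decide it. Of the 13 genes 0 are in another list, the labels name no sort or gate, and no biological explanation was tested because the design has 1 group.

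Peaks crowded into bins that differed between the replicates: bins of 50 kb with at least 20 peaks made up 10.7% of bins in replicate 1 and 6.17% in replicate 2 and held 56.0% and 44.5% of peaks; a bin on chromosome 3 (108950001 to 109000000) held 91 peaks in replicate 1 and 1 in replicate 2. Copy number or an assembly error would crowd the same bins in both libraries. Of the bins crowded in replicate 2, 37.5% were crowded in replicate 1 and 32.9% had 5 or fewer peaks there. Of those crowded in replicate 1, 41.6% had 5 or fewer peaks in replicate 2. Only the bins with 5 or fewer peaks in the other library argue against such a cause. For bins between these limits the cutoff of 20 peaks cannot decide, since it also defined the pattern. Such a cause was not tested for the 1228 bins crowded in both, more than the 799 of random bins matched on GC. Extra DNA in 1 library was argued against for bins crowded in that library only. In those of replicate 1 the median ratio at promoters moved by -0.0166 (log2), where adding the tags of a median crowded-bin peak would give 0.14. In those of replicate 2 the median ratio moved by 0.00831, where the same addition would give -0.22. The bound set beforehand for replicate 1 lay above 0.14, so the comparison rests on these computed shifts. They are too large in size to the extent that some of the added tags would be present without extra DNA. In bins crowded in both libraries the median ratio differed from that in bins crowded in neither. The difference was -0.22 at promoters (3360 regions) and -0.25 at distal regions, and its cause was not tested. A lower local threshold of the peak caller may contribute, but the values cannot decide it. The 5th percentile of tags per peak was 14 in crowded bins and 31 in sparse ones in replicate 1, and 15 and 37 in replicate 2. The median was lower too, at 42 in crowded bins and 81 outside in replicate 1, and 42 and 88 in replicate 2. Bins filled with weak peaks would give such values under 1 common threshold as well. No biological explanation was tested.

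The 100 strongest shared distal regions mostly held no CTCF match and, in the median, no words repeated in the reference. A CTCF match was in 2% of them, against 5.70% of 2000 sampled shared distal regions. A median of 0% of their 24-base words occurred elsewhere in the reference, and 24 of the 100 regions held such words. For the 76 regions without any, this argues against gathered reads of repeats that have copies in the reference. The word count cannot decide on repeats whose other copies are missing from the reference, since it does not see them. Promoters missing from the annotation remain possible for many of the 100 regions. The median ratio of observed to expected CpG of the 100 was 0.785, against 0.238 for all shared distal regions and 0.668 for shared promoters. CpG content alone cannot decide this, since other CpG-rich sequence would give such values too and strength was not matched. The region near Mnt lay 1.33 kb from an annotated start, and that near Wnt7b 52.2 kb. For the 5 strongest, at Limd1, Cd209a, Jarid2, Pak3 and Il1rapl1, the median share of repeated words was 42.3% (6.37 to 87.7%), and repeats and open chromatin cannot be told apart there because the value lies between the bounds set. No biological explanation was tested.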
